A study of Mus musculus with 14 samples.

How the data were processed

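Per the labels, total RNA of embryonic blood was extracted with RNA-Stat 60, labelled with biotin by the one-cycle protocol and hybridized to Affymetrix mouse arrays. Per the submitters' processing notes the log2 values were made by the authors with RMA in Affymetrix Expression Console before they were deposited. The versions of both are not given. The deposited values of 45101 probe sets on 14 arrays were used as they came, and 0 columns belonged to other series. Nothing was normalized again for the main results.

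Probe sets were named by the platform table that came with the values. Of them 34958 carried 1 gene symbol, 932 several, 64 were array controls and 9160 had no symbol here. For 34754 of the 34958 the gene identifier was found in the RefSeq gene table (GRCm38.p6), which was used only for symbols and changed 0 of them. Each of 18194 genes took the probe set with the highest mean over all arrays. Genes with a log2 value of at least 6 in at least 3 of the 14 arrays were kept, which left 7393. Probe sets with several symbols were left out, and those without a symbol were only counted. Some listed genes have no probe set with their symbol and were not analysed here.

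Group means were fitted with lmFit, contrasts.fit and eBayes of limma 3.58.1 in R 4.3.3, with all 14 arrays in 1 model of 4 groups and no covariate. The residual degrees of freedom were 10 and the prior degrees of freedom 2.81. The contrasts were Cbfb+/MYH11 against WT, Cbfb-/- against Cbfb+/+, the difference of these effects, and Cbfb+/+ against WT littermates. The p-values are those of limma's moderated statistic, adjusted by Benjamini and Hochberg over all tested genes of a contrast. A gene was called at an adjusted p under 0.05 and a change of at least 1.5-fold, and only called genes are said to have risen, fallen or changed. Intervals are 95% intervals of the same fit. A change was shared when called in both mutants with the same sign, and lay on one side when called in 1 mutant and in the difference but not in the other mutant. Genes were in the opposite class when called in both with opposite signs.

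The 28 gene lists, with 450 genes of which 411 have a probe set, were written down before the data were examined, as were the contrasts, the filter, the fold floor, the other settings to be tried and the rule for naming genes. They cover red cells (embryonic globins, adult globins, heme synthesis and iron, red cell membrane, erythroid transcription factors, late erythroid maturation), stem and progenitor cells, cytokine receptors and the white cell types (granulocyte, macrophage, mast cell and basophil, lymphoid). They also cover megakaryocytes and platelets, the core binding factor family, genes with reported Runx1 binding or regulation, other tissues (endothelium, mesenchyme, liver or visceral endoderm, neural, trophoblast, epithelium) and responses (cell cycle, p53, interferon, hypoxia and glycolysis, immediate early and stress). The X-inactivation transcript and the Y chromosome complete them. Lists with at least 3 tested genes, 22 in all, were tested by camera of limma with the preset correlation of 0.01 between genes, adjusted over the lists of a contrast. The same test with a correlation estimated from the data, and the rotation test fry, were run beside it.

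Named genes are the 12 with the largest rise and the 12 with the largest fall of each effect, 8 and 8 of the difference, and 5 and 5 of the wild types. To them come up to 4 genes per list with the smallest adjusted p and 16 genes fixed beforehand, 12 of which were tested. Where a list had 5 or fewer genes of a kind, all could be named, and those beyond the rule were chosen after their values were seen. Of the 180 named genes 66 had at least 2 probe sets past the filter, and for 2, Cpe and Laptm5, these disagreed in direction.

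Whether arrays with the same number belong together was taken from the numbers in the labels and checked by correlating, across genes, their deviations from the group mean. In the Cbfb+/MYH11 cross these correlations were 0.521, 0.407, 0.499 and 0.499. Number 1 also correlated with number 2, and number 3 with number 4, while numbers of different pairs gave negative values down to -0.526. In the Cbfb-/- cross the correlations were 0.034, 0.011 and 0.017. The shared unit in the first cross is therefore the array pair and not the number. The first principal component held 53.8% of the variance, the second 26.1% and the third 9.95%.

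A self-test changed 200 of the 7393 genes in 10 simulations of Cbfb+/MYH11 against WT. With array noise only (median SD 0.118), 97.5% of genes changed by a log2 value of 0.8 and 100% of those changed by 1.5 were recovered, with 0 false calls. With pool effects added (median SD 0.211, from the array pairs), 76.3% and 96.6% were recovered. There were then 323.9 false calls in this comparison and 802 in Cbfb-/- against Cbfb+/+, where no gene had been changed. With no gene changed anywhere and pool effects present, the calls were 331.2, 807.7 and, in the difference, 1063.2. The pool effects were drawn independently for each pool and each gene. In the data the deviations were shared between the genotypes of an array pair, and genes of a list were correlated. These counts are therefore only a rough guide to what pool differences could give.

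The other settings changed 1 step at a time. They were quantile normalization across all arrays, centring each array on its median, no filter, a filter at 7, the mean of all probe sets of a gene, and no probe sets ending in _x_at or _s_at. Others were no fold floor, a floor of 2-fold, treat, array weights, eBayes with trend and robust, only the arrays of the groups compared, the replicate number as a block, and each array left out. After the arrays had been seen to fall into pairs, further settings were added. These were the array pair as a block, each pair alone, calls with the same sign in both pairs, arrays averaged to 6 putative pools, and the fit without WT arrays 1 and 2. Calls within each pair outside these settings, and genes whose change differed between the pairs, came from a separate limma model of 6 groups. In it the array pairs of the Cbfb+/MYH11 cross were groups of their own. Its p-values reflect only the spread within a pair, or within a group of the other cross.

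Shared calls were compared with independent lists by Fisher's exact test. Chance was also examined by splitting the 8 or 6 arrays of a cross in all ways (35 and 10 splits) and by drawing 100 regroupings within both crosses for results that use both. A single array was looked at when Dixon's test for 1 outlier passed at 0.05, over 360 sets of a gene and a group. Tests of other explanations for 3 gene groups used the fixed lists, partly without the filter. Those of the array pairs, of neural tissue and, for the endoderm genes, of the range over wild types were chosen after the results were seen. A test of a list was taken as void where most of its members passed the filter only with the arrays of the mutant in which they were high, as for the mast cell list.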

Results

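Gene expression was measured in the peripheral blood of mouse embryos at E12.5 on 14 Affymetrix arrays for the mouse, as log2 values. RNA came from pools of blood of 8 to 10 embryos that shared a genotype. The first cross gave embryos with 1 Cbfb allele replaced by the Cbfb-MYH11 fusion (Cbfb+/MYH11, 4 arrays) and wild-type littermates (WT, 4 arrays). This fusion joins Cbfb, the partner of the Runx transcription factors, to a smooth muscle myosin and is the lesion of a human acute myeloid leukaemia. The second cross gave Cbfb-/- embryos (3 arrays) and their Cbfb+/+ littermates (3 arrays). The labels call the arrays of a group technical replicates, so the p-values measure only the spread between arrays, which may be technical. Array medians lay between 4.27 and 4.46, and between 31 and 35.9% of genes reached a log2 value of 6. The number of arrays limits the precision.

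The targeted gene, Cbfb, was read by 1 probe set. Its log2 values on arrays 1 to 4 were 8.44, 8.56, 6.91 and 7.06 in Cbfb+/MYH11 and 6.63, 6.57, 8.31 and 8.14 in WT. They were 7.03, 6.80 and 6.98 in Cbfb-/- and 6.52, 6.56 and 6.27 in Cbfb+/+. Neither change was called, at 0.33 (limma, Benjamini-Hochberg adjusted p = 0.533; -0.05 after quantile normalization) and 0.48 (adjusted p = 0.453). The position of this probe set relative to the altered part of the gene is not known here, so it checks no genotype label. Mouse Myh11, the gene whose human counterpart gives the other part of the fusion, changed by -0.05 (adjusted p = 0.683) and -0.17 (adjusted p = 0.209) and was not called either. A second Myh11 probe set, below 6 on every array, was at -0.705 and -0.065 (limma over probe sets, adjusted p = 0.0598 and 0.908). It was highest on WT arrays 3 and 4 (4.08 and 4.63).

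The arrays of the Cbfb+/MYH11 cross fell into pairs. Between arrays 1 and 2, or 3 and 4, of a genotype, the SD of the log2 differences across genes was 0.11 to 0.28, against 0.36 to 0.71 between arrays of different pairs. In the Cbfb-/- cross it was 0.20 to 0.22. Afp, a product of liver and yolk sac, was at 11.97 and 11.86 on WT arrays 1 and 2 but at 6.33 and 6.20 on WT arrays 3 and 4. On the Cbfb+/MYH11 arrays it was at 5.71, 5.77, 8.20 and 8.27. Xist, the X-inactivation transcript, had been fixed beforehand as a mark of the mix of sexes in a pool. It was at 7.58, 7.40, 9.29 and 9.14 on WT arrays 1 to 4 and at 8.50, 8.62, 9.45 and 9.51 on the Cbfb+/MYH11 arrays. Arrays of 1 pool would share its level, and Xist followed the array pairs in both genotypes. No Y chromosome gene passed the filter to check this. Changes within each pair are therefore given for a number of genes and lists.

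The comparison of Cbfb+/MYH11 with WT asks what goes with the fusion in embryonic blood. Among the largest rises were those of receptor genes, and among the largest falls those of platelet genes. Csf2rb2, the interleukin 3 receptor beta chain of the mouse, rose 48.0-fold (95% interval 40.1 to 57.6), from 5.55 ± 0.25 to 11.13 ± 0.13 (SD, n = 4, adjusted p = 6.73e-12). Csf2rb, the beta chain shared by the receptors of interleukin 3, interleukin 5 and GM-CSF, rose 16.8-fold, from 7.40 ± 0.08 to 11.47 ± 0.16 (SD, n = 4). Cd200r3, a receptor of basophils and mast cells, rose to 8.57 ± 0.56 from 2.52 ± 0.28, and Ppbp, a platelet chemokine, fell to 3.38 ± 0.12 from 8.19 ± 1.31. Values under the filter of 6 may be background, so changes from or to such values, here and below, are read as lower bounds and their order by size is uncertain.

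Of 7393 tested genes, 2671 were called at an adjusted p under 0.05 and at least 1.5-fold. Of these, 2255 (84.4%) rose and 416 fell. The direction of this count depended on scaling: with quantile normalization 2350 genes were called, 1307 (55.6%) higher and 1043 lower, and 1717 were also called without it. The median change of all tested genes was 0.26, and -0.02 after quantile normalization. It also depended on the filter, at -0.11 over 18194 genes without it and 0.39 with the filter at 7. Relative to the median of 0.26, Csf2rb2 was higher by 5.33, Csf2rb by 3.81 and Cd200r3 by 5.79, and Ppbp was at -5.06 and Pf4 at -3.70. Within the array pairs, 3299 genes were called in arrays 1 and 2 and 2295 in arrays 3 and 4, and 1802 were called with the same sign in both. These calls came from a separate fit with the pairs as groups, whose p-values reflect only the spread within pairs and groups. In simulations with differences between pools as large as those between these pairs, 331.2 genes were called with no change present. The simulated differences were drawn independently for each pool and gene, unlike those in the data, so this count is a rough guide. With the arrays averaged to 6 putative pools, 18 genes passed, among them Csf2rb (adjusted p = 0.034), Csf2rb2 (0.0314), Gata2 (0.0473), Ms4a2 (0.047) and Cd200r3.

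Beside these receptors, the genes with the largest rise were Ms4a2 (to 8.59 from 3.76), the beta chain of the high-affinity IgE receptor, and Fam221a, Npl, Prnp, Flot2, Tmem71, 1700042O10Rik, Pfkp and Gpc4. Npl, a lyase of sialic acid, rose by 4.57 log2 units, the prion protein gene Prnp by 4.35, the glycolytic enzyme Pfkp by 3.87 and the surface proteoglycan Gpc4 by 3.85. After Ppbp, the largest falls were those of the clotting factor subunit F13a1 (fell by 4.23), the macrophage mannose receptor Mrc1 (fell by 3.84), the nicotinic receptor Chrna7 (fell by 3.46), and the platelet chemokine Pf4 (fell by 3.44). Next came Ctla2a, the platelet receptor genes Clec1b (fell by 3.10) and Gp1bb (fell by 3.06), Ctla2b, Il1bos, Tmed8 and the T cell adaptor Skap1 (fell by 2.81). All genes named so far as rising or falling were called within both array pairs, and the plot of single arrays shows this for 6 of them.

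**Figure D1:**
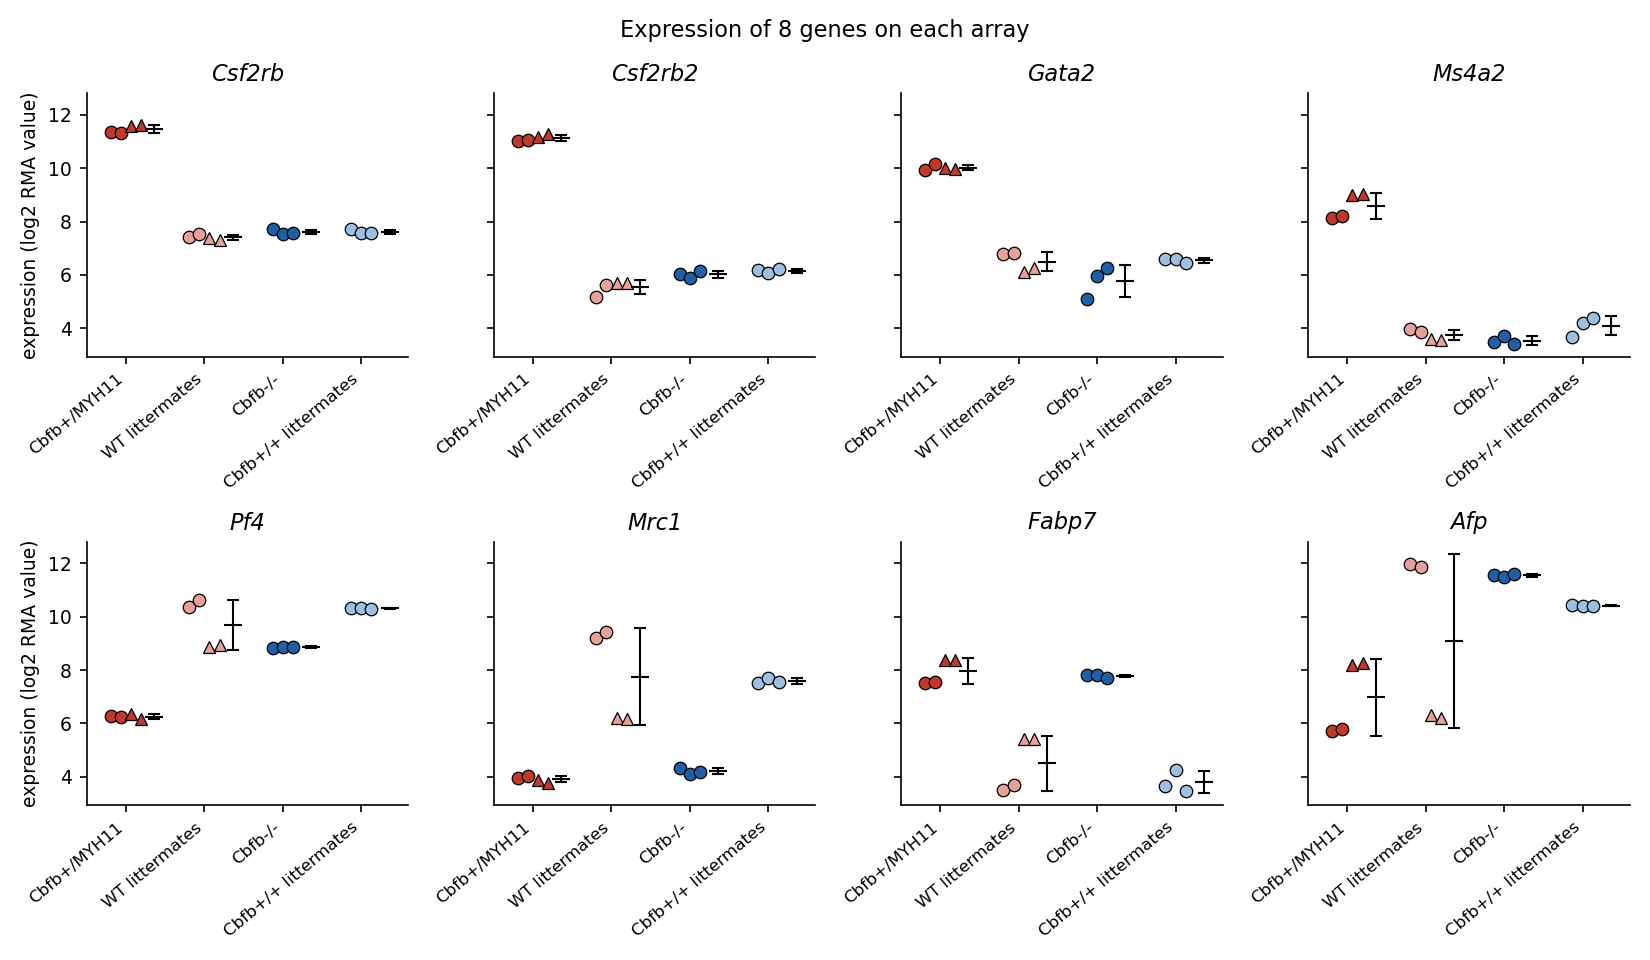
Log2 value (vertical axis) of 8 genes on each of the 14 arrays by genotype (horizontal axis); circles are arrays, triangles arrays 3 and 4 of the Cbfb+/MYH11 cross, and the marks the mean ± SD of 4 or 3 arrays. The 4 Cbfb+/MYH11 arrays of Csf2rb, with a mean of 11.47, lie above all others, while Afp differs between WT arrays 1 and 2 (11.97 and 11.86) and 3 and 4 (6.33 and 6.20).

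From the mast cell, basophil and eosinophil list Ms4a2, the histidine decarboxylase gene Hdc (3.08), the protease gene Cpa3 (2.59) and the amine transporter gene Slc18a2 (1.47) rose. The list fixed 20 genes, and these 4 were the only ones past the filter on dim probe sets, each through the Cbfb+/MYH11 arrays alone. That all 4 rose, and the camera call of the list (adjusted p = 0.00436; adjusted p = 0.175 with an estimated correlation), therefore followed from the filter. Without it the median of the list was -0.03 and there was no call (adjusted p = 0.173), so 4 single genes rose and not the list. Of 5 cytokine receptors, 3 rose, namely both beta chains and the erythropoietin receptor Epor (0.65), while Flt3 (-0.32) and Csf1r (0.23) were not called. Camera did not call that list (adjusted p = 0.085). The Epor call ended without Cbfb+/MYH11 array 2 (0.52) and with quantile normalization (0.32). Of 14 stem and progenitor genes 5 rose and 0 fell. These were the transcription factor genes Gata2 (3.52, from 6.50 ± 0.35 to 10.01 ± 0.10), Lmo2 (1.63), Spi1 (1.38; 0.73 in arrays 1 and 2 and 2.03 in arrays 3 and 4) and Myb (1.35), and Tgm2 (2.10). Camera did not call the list (adjusted p = 0.744), of which 2 genes passed the filter only with the Cbfb+/MYH11 arrays. Kit lay below the filter.

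Most measured platelet and macrophage genes fell. Of 15 measured megakaryocyte and platelet genes, 11 fell, among them Ppbp, Pf4, Clec1b and Gng11 (fell by 0.89). Plek, a platelet kinase substrate, rose (1.18), though only in arrays 3 and 4 (2.39, against -0.02 in arrays 1 and 2) and not with quantile normalization. Gp5, Itga2b and Tubb1 were not called. Camera called the list lower (adjusted p = 4.72e-06; adjusted p = 0.492 with an estimated correlation). The median was -2.35 in arrays 1 and 2 and -0.82 in arrays 3 and 4, and 11 members fell in both. Of 13 monocyte and macrophage genes, 9 fell. Examples were the lysosomal protease Ctss (fell by 2.60) and the signalling adaptors Tyrobp (fell by 2.34) and Fcer1g (fell by 1.75). Laptm5 rose (1.27), by 0.25 in arrays 1 and 2 and 2.28 in arrays 3 and 4, but its other probe sets over the filter gave -0.99, 0.26 and 0.81, so the direction depends on the probe set. Cd14, Csf1r and Lyz2 were not called, and Csf1r went in opposite directions in the pairs (-1.08 and 1.53). The median was -2.46 in arrays 1 and 2 and -1.02 in arrays 3 and 4. Camera gave an adjusted p = 4.07e-04, and an adjusted p = 0.492 with an estimated correlation. The 2 measured granulocyte genes went apart. The granule peroxidase Mpo fell by 2.08, while the transcription factor gene Cebpa rose (2.64).

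Most cell cycle genes rose, and erythroid genes went both ways. Of 28 cell cycle genes 25 rose and 0 fell, for example the proliferation marker Mki67 (1.21), the survivin gene Birc5 (1.62), the spindle gene Tpx2 (1.53) and the cyclin gene Ccne2 (2.17). For this list the adjusted p = 3.35e-04, and adjusted p = 0.614 with an estimated correlation. Ccne1, E2f1 and Ube2c were not called. The median was 2.23 in arrays 1 and 2 and 0.95 in arrays 3 and 4. Without the filter the median level of the list was 6.74 and 6.86 on WT arrays 1 and 2 but 8.10 on WT arrays 3 and 4. On all Cbfb+/MYH11 arrays it was higher, between 9.12 and 9.26. Of 16 late erythroid maturation genes 5 fell, or 10 with quantile normalization and 3 with centred arrays, and 3 fell in both array pairs. The 5 were Bpgm (fell by 1.23), Ube2o, Isg20, Xpo7 and Ube2l6 (fell by 0.66, but -0.55 and not called with arrays centred on their medians). Hemgn, a nuclear protein of erythroid precursors, rose (2.04). This list had an adjusted p = 3.32e-04, and an adjusted p = 0.441 with an estimated correlation.

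Of 18 erythroid transcription factor genes 6 rose, including Ikzf1 (1.35), Klf1 (0.86) and Gata1 (0.77), and Nfia fell by 0.71. The list was not called (adjusted p = 0.541), and its median of 0.22 turned to -0.04 with quantile normalization, which also ended the Gata1 call (0.52). Of 17 heme synthesis and iron genes 6 rose, among them the enzymes Cpox (1.48), Alad (1.01) and Uros (0.98) and the transferrin receptor Tfrc (0.99). Hmox1, the heme-degrading enzyme, fell by 1.19. That list was not called (adjusted p = 0.674), and its median of 0.27 turned to -0.09 with quantile normalization. Of 18 red cell membrane genes 3 rose (Gypc, 0.92; Icam4; Epor) and 3 fell (Tspo2 by 2.59, Cd24a by 1.59, Xk by 1.10), with an adjusted p = 0.0712. Its median of -0.03 was 0.08 with centred arrays and -0.28 with quantile normalization, where 0 rose and 4 fell and Gypc was at 0.54. The anion exchanger Slc4a1 was at -0.26, under the fold floor. The embryonic globins Hbb-bh1 (0.50), Hbb-y (-0.19) and Hba-x (0.03) were not called, although Hbb-bh1 passed with centred arrays (0.61). Their group means of 13.98 and more lay near the highest value on any array (14.55), so these probe sets may be saturated, here and in the other comparisons, and their lack of change says little. The adult globin Hbb-b2 fell by 1.05, which became -0.54 and not called with the mean of its probe sets.

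Some markers of other tissues moved as well. Of 7 liver or visceral endoderm genes 4 fell: Cubn by 1.73, Apoa1 by 1.47, Rbp4 by 1.31 and Apoa2 by 0.93. Afp (-2.10), Alb and Ttr were not called. The adjusted p was 0.0237, and the adjusted p = 0.581 with an estimated correlation. This group followed the array pairs, with a median of -2.43 in arrays 1 and 2 and 0.26 in arrays 3 and 4. Leaving out WT array 1 ended the Apoa1 call (adjusted p = 0.0588), and leaving out WT array 1 or 2 ended those of Cubn (up to 0.07) and of the list (up to 0.0674). The Apoa2 call was lost without any single array except Cbfb+/MYH11 array 3 and WT arrays 3 and 4 (up to 0.141), and with the replicate number as a block (0.0852). Of 4 neural genes Fabp7 (3.46) and Sox2 (2.08; 0.89 in arrays 1 and 2 and 3.26 in arrays 3 and 4) rose, with an adjusted p = 0.732 for the list. Its median was 0.50 in arrays 1 and 2 and 2.14 in arrays 3 and 4. The Sox2 call ended without Cbfb+/MYH11 array 3 or 4 (up to 0.0547). Of 15 mesenchyme genes Col5a1 rose (2.63) and Dcn fell by 0.95, and the median was 0.26 in arrays 1 and 2 and -0.66 in arrays 3 and 4. With quantile normalization 5 fell. The list was not called (adjusted p = 0.0682), but was with the replicate block (0.00778), where Col1a1 (-0.72) was called too. In the epithelium list Krt8 fell by 1.30 (1 of 3 genes; adjusted p = 0.0682).

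Of 14 genes with reported Runx1 binding or regulation, 5 fell (Pf4, Mpo, Alox12, Lat and Myl9, by 2.10 for the last) and 2 rose (Cebpa and Spi1). Their adjusted p = 0.00775 became an adjusted p = 0.492 with an estimated correlation, and the call was lost with quantile normalization (0.0724). The median of the list was -0.63 in arrays 1 and 2 and 0.01 in arrays 3 and 4, and 4 genes fell in both. Runx1 itself was at -0.23 (adjusted p = 0.219). Counts adjusted over the list alone were the same as those over all genes in every list of this comparison. No list called here kept its call with an estimated correlation.

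The comparison of Cbfb-/- with Cbfb+/+ littermates asks what goes with loss of Cbfb in the same blood. Most platelet and macrophage genes and some erythroid genes fell, and among the largest rises were those of Dmrta2, Fabp7 and Sox2. The platelet tubulin Tubb1 fell by 2.62 (6.15-fold; 95% interval 4.24 to 8.92), from 9.28 ± 0.01 to 6.65 ± 0.07 (SD, n = 3, adjusted p = 3.97e-05). Dmrta2, a transcription factor gene of the forebrain, rose from 4.01 ± 0.26 to 8.22 ± 0.15 (SD, n = 3, adjusted p = 9.39e-06). Csf2rb (0.00, adjusted p = 0.979) and Csf2rb2 (-0.14, adjusted p = 0.435) were not called.

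Of the 7393 genes, 1935 were called, 1443 (74.6%) higher and 492 lower. With quantile normalization the split was 1008 (52.7%) against 904, and 1495 genes were shared. The median change of all tested genes was 0.13, and -0.04 after quantile normalization. Without the filter it was -0.05, and with the filter at 7 it was 0.17. Relative to the median of 0.13 Dmrta2 was higher by 4.07, and Mrc1 was at -3.52. The simulation with independent differences between pools called 807.7 genes here with no change present. In a fit to putative pools this cross leaves 1 pool per genotype, each assumed to vary like the pools of the other cross. Limma then called 0 genes, with 336 at an unadjusted p under 0.05.

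The 12 largest rises were, beside Dmrta2, those of Tubb2b (4.61), Zic1 (4.58), Fabp7 (3.98, from 3.80 ± 0.41 to 7.78 ± 0.06), Lhx2 (3.85) and Sox2 (3.61), then Pfn2, Dpysl3, Sbk1, Fez1, Nnat (3.41) and Cpe (3.32). Some were about as high on WT arrays 3 and 4 of the other cross as in Cbfb-/-, such as Sbk1 (7.78 and 7.82 against a mean of 7.93), Cpe (7.90 and 7.73 against 7.78) and Dpysl3 (6.82 and 6.64 against 6.90). Pfn2 (7.36 and 7.34) and Tubb2b (7.15 and 7.11) were partly so, while Dmrta2, Lhx2 and Sox2 were low there. Wild-type blood can thus carry several of these transcripts at that level. Sbk1 lost its call without any one of the 6 arrays of this cross (adjusted p up to 0.0829). Cpe lost it without Cbfb-/- array 1 or 3 or Cbfb+/+ array 2 (up to 0.0581), and another of its probe sets fell by 1.79. The largest falls were those of Mrc1 (fell by 3.39), the platelet genes Gp1bb (fell by 3.13) and Ppbp (fell by 2.84), and the complement gene C1qc (fell by 2.83). Next were F13a1 (fell by 2.73), Ms4a6b, Plaat3, Ctla2b, Gdpd3, the macrophage growth factor receptor Csf1r (fell by 2.39) and Arhgdib.

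Of 15 megakaryocyte and platelet genes 13 fell and 0 rose (adjusted p = 3.59e-08; adjusted p = 0.267 with an estimated correlation), including the integrin gene Itga2b (fell by 1.66). Of 13 monocyte and macrophage genes 12 fell (adjusted p = 2.30e-07; adjusted p = 0.267 with an estimated correlation), for instance Tyrobp (fell by 2.35), Ctss (fell by 2.30) and Fcer1g (fell by 2.03). Only Ccr2 was not called. Both granulocyte genes fell, Mpo by 2.15 and Cebpa by 0.74, the latter not without Cbfb-/- array 1 or 3 or Cbfb+/+ array 2 (adjusted p up to 0.0621). Of 14 genes with reported Runx1 binding or regulation 10 fell, 11 when adjusted over the list alone, and 0 rose (adjusted p = 2.30e-07; adjusted p = 0.22 with an estimated correlation). Examples were Mpo, Itga2b, Csf1r and Myl9 (fell by 1.12). Runx1 was at -0.32 (adjusted p = 0.174). Of 4 mast cell and basophil genes Slc18a2 fell by 1.85 and Cpa3 by 0.78 (adjusted p = 0.0118; adjusted p = 0.209 with an estimated correlation, and 0.0609 with quantile normalization). All 4 passed the filter only with the Cbfb+/MYH11 arrays. Cpa3, for example, was at 4.00, 4.17 and 3.85 in Cbfb-/- against 5.12, 4.70 and 4.55. These falls and the list call thus compare dim values that may be background. Of 5 cytokine receptors Csf1r fell. That list's adjusted p = 0.0489, or adjusted p = 0.22 with an estimated correlation, passed 0.05 with quantile normalization (0.0617) and without any of 6 single arrays, namely WT array 2, Cbfb-/- arrays 2 and 3 and the Cbfb+/+ arrays (up to 0.0659).

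The erythroid lists had medians between -0.55 and -0.34, and most of their members were not called. Of 18 erythroid transcription factor genes 7 fell and 0 rose (adjusted p = 2.30e-07; adjusted p = 0.22 with an estimated correlation), for example Myb (fell by 1.57), E2f2 (fell by 1.28), Foxo3 (fell by 1.10) and Lmo2 (fell by 0.71). Gata1 (-0.43) and Klf1 (-0.24) were not called. Of 16 late erythroid genes 5 fell: Ypel4 by 1.11, Xpo7 by 0.99, Ulk1 by 0.72, Ube2o by 0.69 and Mxi1 by 0.66 (adjusted p = 7.98e-07; adjusted p = 0.209 with an estimated correlation). Of 18 red cell membrane genes 6 fell, among them Tspo2 (fell by 2.18) and Add2 (fell by 0.63), while Slc4a1 (-0.18) was not called (adjusted p = 1.53e-06; adjusted p = 0.284 with an estimated correlation). Of 17 heme and iron genes Slc25a38 fell by 0.77 and Hmox1 by 0.63 (adjusted p = 4.58e-05; adjusted p = 0.284 with an estimated correlation). With quantile normalization 12, 9, 11 and 7 genes of these lists fell and 0 rose. The embryonic globins Hba-x (0.08), Hbb-bh1 (0.04) and Hbb-y (0.03) were not called, and the adult globin Hbb-b2 fell by 0.74.

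Of 28 cell cycle genes 14 rose, or 15 when adjusted over the list alone (adjusted p = 7.83e-04; adjusted p = 0.596 with an estimated correlation). Examples were the DNA replication genes Rrm1 (1.47) and Rrm2 (1.00), the spindle gene Tpx2 (0.83) and the checkpoint gene Bub1b (0.95). Without the filter the median level of the list was 8.52 to 8.80 in Cbfb-/- and 7.76 to 7.87 in Cbfb+/+. In the other cross it was 6.74 and 6.86 on WT arrays 1 and 2 but 8.10 on WT arrays 3 and 4. Wild-type arrays thus varied by more than the median rise of 0.91. Of 14 stem and progenitor genes 3 rose (Sox4, 2.62; Prom1, 2.38; Bmi1, 1.85) and 3 fell (Myb, Lmo2 and Gata2), or 4 over the list alone. Gata2 fell by 0.78. That call ended without Cbfb-/- array 1 (-0.44) or Cbfb+/+ array 1 or 2 (adjusted p up to 0.104) and with the mean of its probe sets (-0.57). The list's median was -0.15 and its mean 0.17, and camera put it lower without a call (adjusted p = 0.136). Of its 14 genes 2 passed the filter only with the Cbfb-/- arrays and 2 only with the Cbfb+/MYH11 arrays.

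Some markers of other tissues rose in the Cbfb-/- arrays. Of 4 neural genes Fabp7, Sox2 and Nes (1.11) rose (adjusted p = 0.0116; adjusted p = 0.267 with an estimated correlation), and the list call was lost with the mean of probe sets (0.0717). Of these 4 genes 2 passed the filter only with the Cbfb-/- arrays. Of 7 liver or visceral endoderm genes 5 rose: Cubn (2.76), Ttr (2.35), Rbp4 (1.95), Apoa1 (1.58) and Apoa2 (1.51), of which Cubn and Rbp4 passed the filter only with the Cbfb-/- arrays. Afp (1.13, adjusted p = 0.525) was not called. The list was not called (adjusted p = 0.0933), but was with quantile normalization (0.0432). Ttr lost its call without any one of the 6 arrays of this cross (adjusted p up to 0.0661). Of 15 mesenchyme genes the cartilage collagen Col2a1 (2.22), Meox1 (1.78) and Twist1 (1.12) rose (adjusted p = 0.23), and 3 of the 15 passed the filter only with these arrays. The 3 epithelial genes were not called (adjusted p = 0.489). The plot of gene lists sets these medians side by side.

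**Figure D2:**
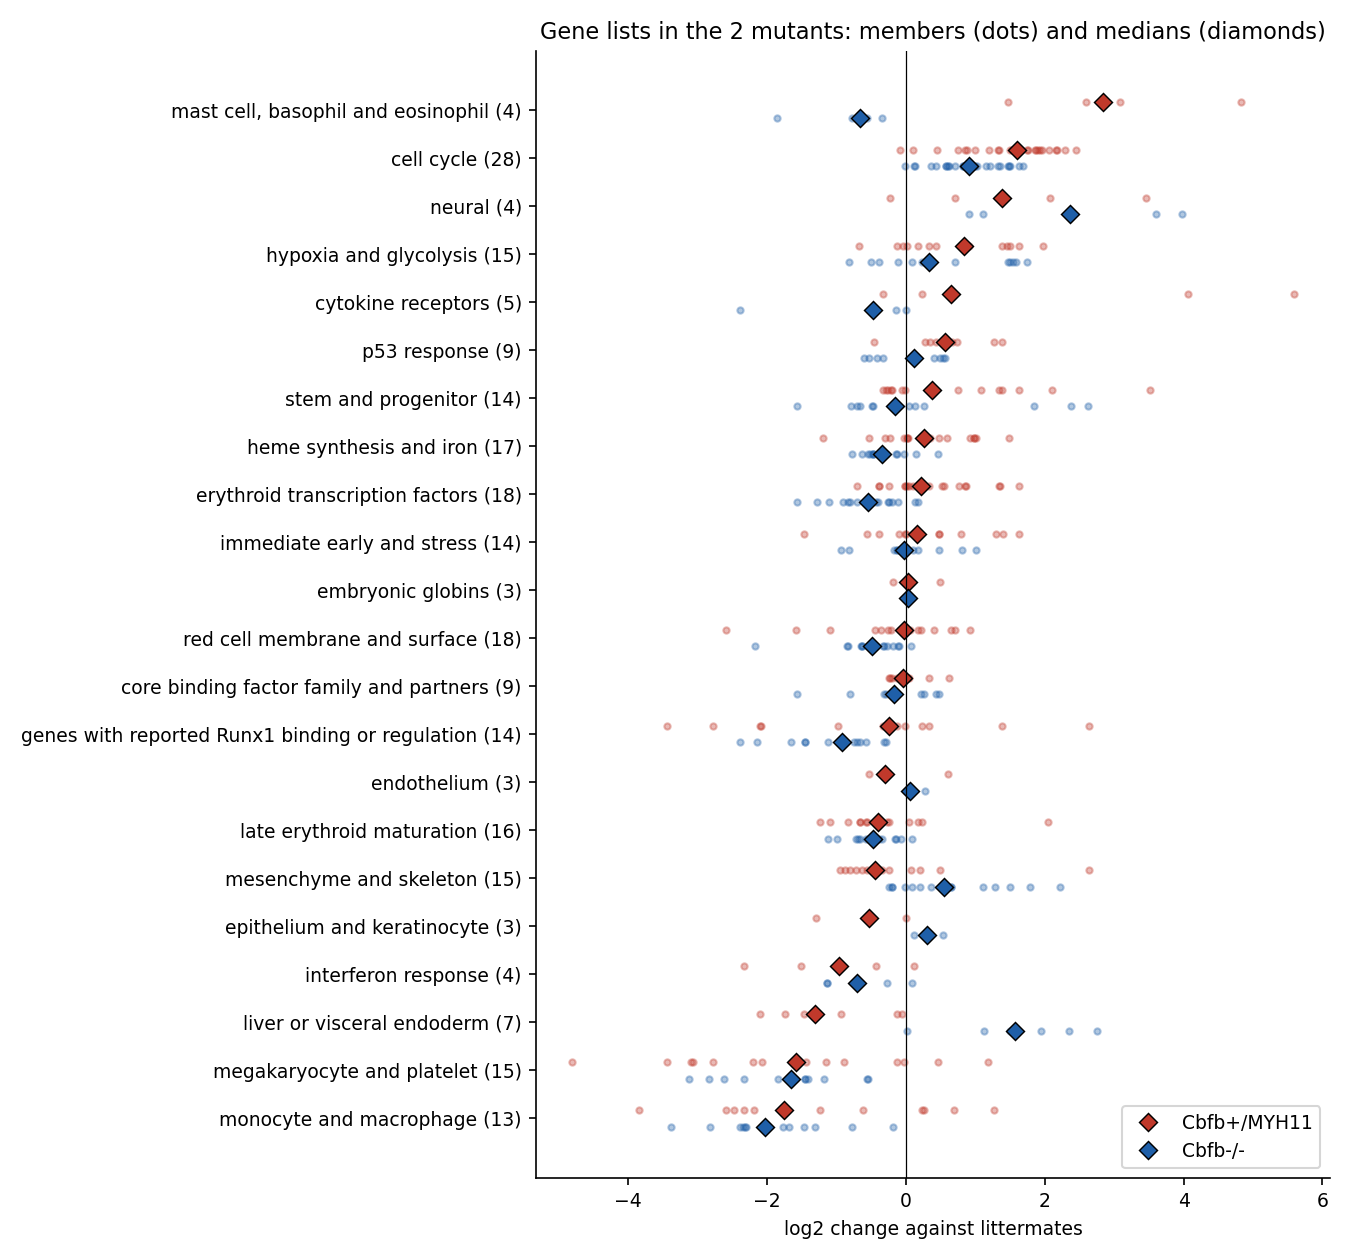
Log2 change (horizontal axis) of the genes of 22 lists (vertical axis) in Cbfb+/MYH11 against WT (red) and in Cbfb-/- against Cbfb+/+ (blue); dots are genes and diamonds list medians. The mast cell median, of 4 genes that the Cbfb+/MYH11 arrays brought past the filter, is 2.84 in red and -0.67 in blue, and the cell cycle medians are 1.60 and 0.91; with quantile normalization the red medians of the erythroid transcription factor (0.22) and heme lists (0.27) fall below 0.

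The series asks which changes of the fusion do not come with loss of Cbfb. The effects of both mutations, each against its own littermates, were therefore compared. The rises of Csf2rb, Csf2rb2 and Gata2 in Cbfb+/MYH11 had no counterpart in Cbfb-/-, while falls of platelet and macrophage genes were in part shared. The effect on Csf2rb2 was 52.8-fold larger in Cbfb+/MYH11 (95% interval 40 to 69.6, adjusted p = 1.47e-09, n = 4 and 3 arrays per group) and that on Csf2rb 16.7-fold (13.6 to 20.6). For Gata2 it was 19.7-fold, with log2 changes of 3.52 and -0.78.

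The effects differed for 1548 genes, with 1099 (71.0%) more positive in Cbfb+/MYH11 and 449 more negative. With quantile normalization there were 827 (59.0%) and 574. The lean also went with the array pairs, with 1278 and 1092 from arrays 3 and 4 of the Cbfb+/MYH11 cross alone, and it turned to 1158 and 1199 without WT arrays 1 and 2. With no change present the simulation with independent pool differences called 1063.2. The fit to putative pools called 0 (limma, 572 at an unadjusted p under 0.05). After Cd200r3 (6.21), Csf2rb2 and Ms4a2 (5.38), the largest positive differences were those of Fam221a (4.72), Rac2 (4.48), Npl, Tmem71 and 1700042O10Rik (4.33). Rac2 changed by 2.70 in Cbfb+/MYH11 and -1.78 in Cbfb-/-. The largest negative ones were those of Cubn (-4.49), Dmrta2 (-3.80), the neural progenitor gene Sox3 (-3.48), Prap1 (-3.44), the retinol carrier Rbp4 (-3.26), the cardiac actin Actc1 (-3.11), Lhx2 (-3.06) and Apoa1. The Prap1 call was lost without Cbfb-/- array 2 or 3 or any Cbfb+/+ array (adjusted p up to 0.0562). That of Actc1 was lost without Cbfb+/MYH11 array 1 or 2 or any array of the Cbfb-/- cross (up to 0.0693).

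The mast cell and basophil genes Hdc (3.42), Cpa3 (3.37) and Slc18a2 (3.32) had a more positive effect in Cbfb+/MYH11, as Ms4a2 did. The call of their list (adjusted p = 1.53e-05, and 0.0149 with an estimated correlation) again used only genes chosen by the filter. Without the filter the list was still called (camera adjusted p = 0.00124), at a median of 0.19. Of 5 cytokine receptors 4 had a more positive effect, with Csf1r at 2.62 and Epor at 1.13 (adjusted p = 2.78e-04). Among the camera calls of the 3 comparisons, the mast cell list aside, only that of the cytokine receptors held with an estimated correlation, at 0.020. Both lists were at 0.0502 once the array pair was also a block. Of 18 erythroid transcription factor genes 12 differed, all more positive in Cbfb+/MYH11, for example Myb (2.91), Lmo2 (2.34), Ikzf1 (1.55), Gata1 (1.20) and Klf1 (1.10). The adjusted p was 1.53e-05, and the adjusted p = 0.314 with an estimated correlation. Of 17 heme and iron genes 8 did, such as Ppox (1.40), Cpox (1.33), Tfrc (1.28) and Uros (1.26). The adjusted p was 4.69e-04, and the adjusted p = 0.551 with an estimated correlation. The red cell membrane list (5 more positive, such as Gypc at 1.44, and Cd24a more negative, -1.08, or 2 and 1 with quantile normalization), the late erythroid list (3 and 2, or 4 and 2 over the list alone) and the globins (0) were not called, with adjusted p = 0.237, 0.841 and 0.973. Hbb-bh1 was at 0.46, Hbb-y at -0.23, Hba-x at -0.06 and Slc4a1 at -0.08. Runx1 (0.08), Cbfb (-0.15) and Myh11 (0.13) did not differ past the test.

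Platelet and macrophage lists did not differ as wholes (both adjusted p = 0.656), but single members did. Tubb1 (3.08), Plek (2.78), Itga2b (1.53) and Gp5 (1.38) were more positive in Cbfb+/MYH11 and Pf4 more negative (-1.99). The median of that list was -0.23 and its mean 0.06. Of the macrophage genes Laptm5 (3.04), Csf1r (2.62), Lyz2 (2.37) and Cd14 (1.04) were more positive. The Laptm5 value reversed to -0.24 without probe sets ending in _x_at or _s_at. The Cd14 call was lost without any of 11 single arrays, all but WT arrays 1 and 2 and Cbfb-/- array 1 (adjusted p up to 0.12). The stem list had 5 more positive genes (Gata2, Myb, Lmo2, Tgm2 and Spi1) and 1 more negative (Prom1, -2.43), with a median of -0.09 and a mean of 0.58 (adjusted p = 0.405). Cebpa differed by 3.39, and Mpo by 0.07 was not called. Of 14 genes with reported Runx1 binding or regulation 6 were more positive, among them Nfe2 (0.91), and Pf4 and Myl9 more negative (adjusted p = 0.387). Of 28 cell cycle genes 4 were more positive (Ccnb2, 1.42; Birc5, 1.05; Ccna2, 0.96; Mki67, 0.78; adjusted p = 0.207).

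Liver or visceral endoderm markers were more negative in Cbfb+/MYH11 for 4 of 7 genes, or 5 over the list alone (adjusted p = 6.51e-04; adjusted p = 0.527 with an estimated correlation). In the mesenchyme list 3 were more negative, among them Col2a1 at -2.01, and Col5a1 more positive (adjusted p = 0.00199; adjusted p = 0.633 with an estimated correlation). Of 3 epithelial genes Krt8 (-1.60) and Krt18 (-1.06) were more negative. The epithelial adjusted p = 0.0296, or adjusted p = 0.314 with an estimated correlation, was 0.082 with the replicate block. It was also lost without WT array 1 or 2 or Cbfb+/+ array 1 (up to 0.0571). Of the neural genes Nes differed (-1.34; list adjusted p = 0.0681).

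Of the called genes 914 changed the same way in both mutants, 770 higher and 144 lower. Independent lists of these sizes would share 440.1 and 27.7 (Fisher's exact odds ratios 3.44 and 10.1, p = 8.21e-92 and 1.91e-70, across genes, which are not independent replicates). The crosses share no control array. Pearson's r of the effects across the 7393 genes was 0.41. With quantile normalization the shared split was 382 (51.5%) higher and 360 lower, from 84.3% higher. A further 713 genes changed in Cbfb+/MYH11 with no call in Cbfb-/- and a called difference, 634 (88.9%) higher and 79 lower, or 391 (71.2%) and 158 with quantile normalization. Csf2rb and Csf2rb2 were among them. For 394 genes the change lay on the Cbfb-/- side only, 236 higher and 158 lower. This lean turned to 109 higher and 132 lower with the filter at log2 of 7, and with arrays 3 and 4 of the Cbfb+/MYH11 cross alone there were 650 and 181. Another 95 genes moved in opposite directions, 81 of them higher in Cbfb+/MYH11. That direction did not hold with arrays 3 and 4 alone (105 higher and 109 lower) or without WT arrays 1 and 2 (102 and 200). The plot of effects shows these classes.

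**Figure D3:**
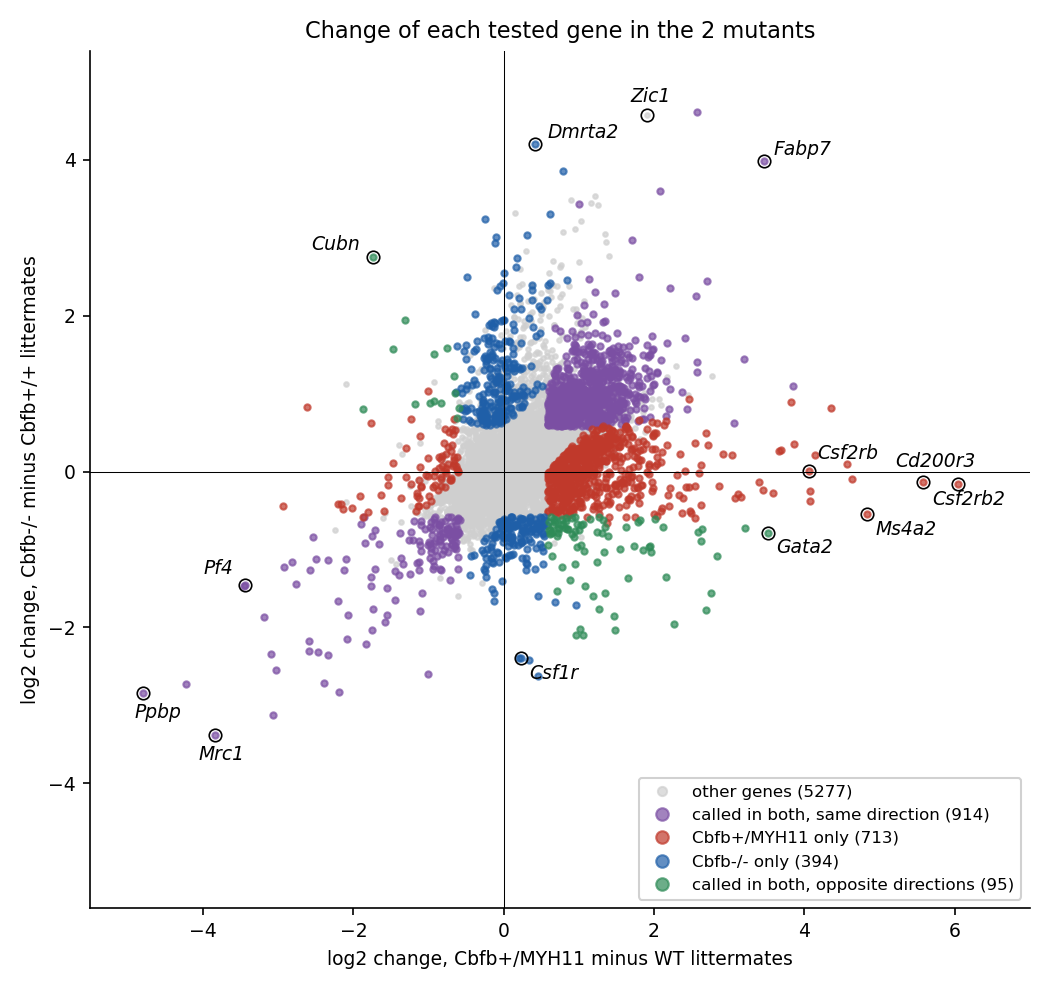
Log2 change of each of 7393 genes (points) in Cbfb+/MYH11 against WT (horizontal axis) and in Cbfb-/- against Cbfb+/+ (vertical axis), coloured by class. The 914 genes changed alike lie in the upper right and lower left; Csf2rb lies at 4.07 and 0.00, Mrc1 at -3.84 and -3.39.

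The wild types of the crosses were compared as a background with the same Cbfb genotype. Of the tested genes 831 differed, 405 higher and 426 lower in Cbfb+/+ littermates than in WT. The direction depended on the array pair, with 1050 higher and 434 lower against WT arrays 1 and 2 alone, and 514 higher and 1455 lower against WT arrays 3 and 4 alone. Higher were Nagpa (1.93), the lectin Lgals3 (1.88), Cdk5rap1, Lhx2 and C1qtnf4 (1.64), and lower were Zfp874a (-3.25), Actc1 (-2.85), the smooth muscle kinase gene Mylk (-2.17), Meis2 (-2.03) and the noncoding RNA Malat1 (-1.92). Myh11 (0.67), Klf1 (0.66) and Csf2rb2 (0.61) were also higher, the last not without WT array 1 (0.48) or Cbfb+/+ array 3. Csf2rb (0.21, adjusted p = 0.143), Gata2 (0.06), Gata1 (0.46), Runx1 (-0.31), Cbfb (-0.96, adjusted p = 0.164), Slc4a1 (-0.12) and the embryonic globins Hbb-bh1 (0.30), Hbb-y (0.08) and Hba-x (0.03) were not called. The Meis2 call was lost without any single array except WT arrays 1 and 2 (adjusted p up to 0.114), and those of Lhx2 and Mylk without Cbfb+/+ array 1 (0.0532 and 0.0522). The fit to putative pools called 0 (limma, 414 at an unadjusted p under 0.05).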

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

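The tests of array pairs, of neural tissue and, for the endoderm genes, of the range over wild types were chosen after the results had been seen. Among 360 sets of a gene and a group, 6 held 1 array further from the rest than Dixon's test allows at 0.05. Chance alone gives about 1 such set in 20.

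Of these 6 sets, 5 lay in the WT littermates of the Cbfb+/MYH11 cross. WT array 2 stood above the others for the cell cycle inhibitor Cdkn1a (gap ratio 0.966; 6.43, 6.67, 6.43 and 6.43), Mdm2 (0.928; 7.61, 7.98, 7.60 and 7.63), the glucose transporter Slc2a1 (0.854) and the erythroid membrane gene Tspo2 (0.884; 9.57, 10.00, 9.52 and 9.51). WT array 1 stood below for Csf2rb2 (0.863; 5.17, 5.62, 5.69 and 5.70). Cbfb+/MYH11 array 3 stood above for Nes (0.866; 7.08, 7.06, 7.25 and 7.05). All arrays were kept.

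In the separate fit with the array pairs as groups, the change from WT to Cbfb+/MYH11 differed between the pairs for 1446 genes. Of these, 1125 were more positive in arrays 1 and 2, the first pair, than in arrays 3 and 4, and 321 more negative. The Cbfb probe set went from 1.90 in the first pair to -1.24 in the second, a difference of 3.144 (limma adjusted p = 1.23e-07). The sign of its change therefore depends on the pair, with high values on Cbfb+/MYH11 arrays 1 and 2 and on WT arrays 3 and 4. Csf2rb (3.88 and 4.26), Csf2rb2 (5.63 and 5.54) and Gata2 (3.25 and 3.78) were higher in Cbfb+/MYH11 in both pairs, and an exchange of genotypes within a pair would have reversed these genes there too. Afp showed -6.17 and 1.97, a difference of -8.14 (adjusted p = 5.87e-14). Among the probe sets without a symbol here, 145 were higher and 46 lower in Cbfb+/MYH11, and 106 were higher and 61 lower in Cbfb-/-. These may belong to genes that could not be named. They also lean to higher values, though less than the called genes with a symbol (84.4% and 74.6% higher). Only the 718 of these probe sets past the same filter were tested. The median change of genes with a symbol was below 0 without that filter, so this lean is no separate evidence. Quantile normalization, which reduced those shares to 55.6% and 52.7%, was not tried on these probe sets.

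The rise of 4 mast cell and basophil genes in Cbfb+/MYH11 was weighed against other sources. Admixed adult blood would bring granulocyte and lymphoid transcripts. Their median over 37 genes without the filter was -0.301, with a 95% upper bootstrap bound of -0.231. Only 2 granulocyte genes and 1 lymphoid gene passed the filter. Most of the 37 were thus dim, and the lack of a rise in their median says little. S100a8 and S100a9, abundant in adult granulocytes, stayed at 3.54 and 4.13 against 5.04 and 4.33 in WT. These 2 genes argue against that source. The median change within the array pairs (2.667 and 3.006) and the range over 3 sets of wild-type arrays (0.395, against a change of 2.84) cannot decide, because the filter kept only genes high on the Cbfb+/MYH11 arrays and dim on all others. Of the single genes Ms4a2 kept its call in the fit to putative pools (limma adjusted p = 0.047), while Cpa3 (0.0554), Hdc (0.0652) and Slc18a2 (0.119) did not. Averaging left their changes as they were (2.59, 3.08 and 1.47), and with 2 pools per group a lost call says little. A difference between pools stays open for those 3 and is not excluded for Ms4a2. Its adjusted p lay just under 0.05, and the pools were inferred from these same arrays. Ms4a2 too passed the filter only through the Cbfb+/MYH11 arrays.

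The fall of liver or visceral endoderm genes in Cbfb+/MYH11 was weighed in the same way. The median change was -2.428 in arrays 1 and 2 and 0.257 in arrays 3 and 4. Among wild-type arrays the list ranged over 1.504, more than the change of -1.31. Differences between pools, such as a varying share of liver or yolk sac material taken up with the blood, could therefore produce this fall without any effect of the fusion. Pools of single embryos dissected alike would separate these.

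The rise of neural genes in Cbfb-/- was weighed against RNA from neural tissue. Without the filter the median change of the neural list was 0.831, with 11 of 12 genes higher, including Fabp7 (3.98), Tubb3 (2.13) and Map2 (2.13) but not Pax6 (-0.06). Most of the same genes were also higher in Cbfb+/MYH11, such as Fabp7 (3.46), Map2 (1.44), Nefl (1.24) and Tubb3 (1.08), but not Nes (-0.23) or Pax6 (-0.42). Neural tissue in the pooled blood could give these values in both mutants. In Cbfb+/MYH11 the median of the 4 tested genes was 0.50 in arrays 1 and 2 and 2.14 in arrays 3 and 4. Fabp7 and Sox2 rose in both mutants, so their rise is not particular to Cbfb-/-. The effects on Nes (-1.34), Dmrta2 (-3.80) and Sox3 (-3.48) did differ, with higher values on the Cbfb-/- side. Among wild-type arrays the list ranged over 1.191, against a change of 2.36 in the 4 tested genes. As 2 of these passed the filter only with the Cbfb-/- arrays, this leaves open how much pools vary. Blood from further Cbfb-/- litters, or in situ staining of circulating cells for Fabp7, would tell contamination from expression in blood cells.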

How the results depend on the processing

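The array pair, the putative pools and the fit without WT arrays 1 and 2 were added after the results had been seen. Each setting below gives genes called, beside 2671 (Cbfb+/MYH11), 1935 (Cbfb-/-), 1548 (difference), 831 (wild types), 914 (shared), 713 (Cbfb+/MYH11 only), 394 (Cbfb-/- only) and 95 (opposite). The cause of a move was not tested unless the construction of a setting shows it.

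Stricter and looser thresholds moved counts by construction. Without a fold floor there were 4622 in Cbfb+/MYH11, 3218 in Cbfb-/-, 1919 between wild types, 1782 shared and 361 opposite. At 2-fold there were 1173, 787, 762, 153, 278 shared, 334, 171 and 22. Treat, which tests against 1.5-fold, gave 893, 118, 369, 33, 25 shared, 227, 40 and 6. A filter at 7, which left 4358 genes to test, gave 1029 in the difference and 241 in Cbfb-/- only. The mean of probe sets, with 4921 genes tested, gave 1701 in Cbfb+/MYH11, 428 between wild types, 600 shared and 62 opposite. As 7393 genes were tested in the main fit, lower counts in these 2 settings do not by themselves mean lost calls. Without probe sets ending in _x_at or _s_at no count moved by more than 1.5 times, but the difference for Laptm5 turned to -0.235.

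Array weights gave 2402 in the difference (1301 more positive and 1101 more negative), 1901 between wild types (507 higher and 1394 lower), 839 in Cbfb-/- only and 213 opposite. They turned Cbfb in Cbfb+/MYH11 to -1.076, Apoa2 to 0.131 and the Ifi27l2a difference to 0.683. They were lowest for WT arrays 1 and 2 (0.075 and 0.098), and their fit did not converge. Fry called the embryonic globins at medians of 0.029 (Cbfb+/MYH11, adjusted p = 4.03e-06) and -0.055 (difference, adjusted p = 0.00716), with the sign opposite to camera.

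With the array pair as a block, 624 genes were called in Cbfb-/- only. Arrays 1 and 2 alone gave 2375 in the difference, 1484 between wild types and 1404 shared, with Cbfb at 1.419 in the difference. Arrays 3 and 4 alone gave 2370, 1969, 831 in Cbfb-/- only and 214 opposite, with Cbfb at -1.241 and Apoa2 at 0.257 in Cbfb+/MYH11 and Ifi27l2a at 0.769 in the difference. Calls alike in both pairs left 424 between wild types. Without WT arrays 1 and 2 there were 2357 in the difference, 1943 between wild types, 588 shared, 861 in Cbfb-/- only and 302 opposite, and Ifi27l2a was at 0.701 in the difference.

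The 6 putative pools left 18 genes in Cbfb+/MYH11 and 0 in every other count, with limma calling 2152, 336, 572 and 414 genes at an unadjusted p under 0.05. The replicate block gave 2753, 2127, 1899, 1070 shared, 793, 557 and 101. It ended the calls of Apoa2 in Cbfb+/MYH11 (0.0852) and Ttr in Cbfb-/- (0.0671), and of the p53 (0.0504) and epithelium lists (0.082) in the difference. It made those of Col1a1 in Cbfb+/MYH11, Pdgfra in Cbfb-/- (0.0325), Stmn2 and Xist in both, Xist and Rsad2 in the difference and mesenchyme in Cbfb+/MYH11. It changed no other call of a named gene or list.

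Leaving out single arrays gave 2258 to 3014, 1550 to 2080, 1296 to 1686, 712 to 1058, 670 to 1125 shared, 621 to 835, 310 to 549 and 85 to 112. Over the settings fixed beforehand, named genes stayed as they were, called or not, 8508 times, lost a call 339 times, gained one 119 times and reversed 4 times. For lists these were 1211, 59, 48 and 2. In the added settings these were 1370, 255, 53 and 5 for genes and 157, 33, 8 and 0 for lists. The settings fixed beforehand include each array left out in turn, also for effects of the cross it does not belong to. There the change itself could not move, so the large counts of unmoved calls overstate stability. Of the losses 229 came with the pools, 101 with treat, 25 with camera's estimated correlation and 27 with the array pair beside it. Quantile normalization ended 15 and made 16 gene calls. With 2 or 1 putative pools per group, the number of pools limits what can be told from pool differences.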

Other observations

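The tests of array pairs, of neural tissue and, for the endoderm genes, of the range over wild types were chosen after the results were seen. Some glycolysis genes rose in both mutants. Of 15 genes of the hypoxia and glycolysis list 8 rose in Cbfb+/MYH11, among them the glucose transporters Slc2a3 (1.98) and Slc2a1 (1.39) and the lactate dehydrogenase Ldha (1.64), and Hk1 fell by 0.68 (camera adjusted p = 0.274). In Cbfb-/- 6 rose, such as Ldha (1.51) and Pgk1 (1.58), and Slc2a1 fell by 0.83 (adjusted p = 0.35). The difference was more positive for Slc2a1 (2.21) and Slc2a3 (1.69) and more negative for Pkm (-1.31), with a median of -0.05 and a mean of 0.17 (adjusted p = 0.973). Of 9 p53 response genes 4 rose in Cbfb+/MYH11 (Cdkn1a, 1.38; Ccng1, 1.27; Ei24, 0.73; Aen, 0.66; adjusted p = 0.0712). With quantile normalization 2 rose and 1 fell, and the median of 0.56 was 0.20. Bbc3 fell by 0.61 in Cbfb-/- (adjusted p = 0.739; median 0.12, direction lower, and -0.09 with quantile normalization). There 2 rose and 0 fell with centred arrays, and 0 rose and 3 fell with quantile normalization. The difference was more positive for 5 (adjusted p = 0.0296; adjusted p = 0.255 with an estimated correlation, 0.0504 with the replicate block and 0.0837 with quantile normalization).

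Of 4 interferon genes Rsad2 (fell by 2.33) and Ifi27l2a fell in Cbfb+/MYH11 (adjusted p = 0.0485; adjusted p = 0.492 with an estimated correlation). The median was -1.64 in arrays 1 and 2 and -0.17 in arrays 3 and 4, and 7 single arrays left out ended the call (up to 0.0711). In Cbfb-/- Rsad2 fell by 1.13 (adjusted p = 0.172), and 0 differed between the effects (adjusted p = 0.37), though Rsad2 did with the replicate block. Of 14 immediate early and stress genes 4 rose in Cbfb+/MYH11 (Hspa1b, 1.64; Jun, 1.41; Hspa1a; Hspa8) and Fos fell by 1.47. The median was 0.16 with a camera direction downward (adjusted p = 0.675), and -0.19 with quantile normalization. In Cbfb-/- 2 rose and 2 fell (median -0.03, mean 0.02, adjusted p = 0.397), and in the difference 3 were more positive and 1 more negative (adjusted p = 0.973). Of 9 core binding factor genes Cbfa2t3, a corepressor, rose in Cbfb+/MYH11 (0.62; median -0.05, mean 0.02, adjusted p = 0.26), though not without Cbfb+/MYH11 array 3 or 4 or WT array 4 (0.54), nor with quantile normalization (0.23) or the mean of probe sets (0.09). It fell by 0.80 in Cbfb-/-, with Runx1t1 (fell by 1.56; adjusted p = 0.172), and both differed (adjusted p = 0.973). Of 3 endothelial genes Egfl7 rose in Cbfb+/MYH11 (0.61, adjusted p = 0.301; 0 rose and 2 fell with quantile normalization, and without Cbfb+/MYH11 array 3 or WT array 3 it was not called), 0 were called in Cbfb-/- (0.842), and Esam differed (-0.59, adjusted p = 0.37). The single tested lymphoid gene Zap70 (-0.30), trophoblast gene Hand1 (-0.36) and X-inactivation transcript Xist (0.67) were not called in Cbfb+/MYH11. Zap70 was called lower with quantile normalization (-0.71), and Xist higher with the replicate block (adjusted p = 0.00705). Of the Y chromosome list 0 genes were tested.

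Both receptor beta chains, Gata2 and 4 mast cell genes rose in Cbfb+/MYH11 and not in Cbfb-/-. This may come from a circulating progenitor of the basophil or mast cell line that the fusion produces and loss of Cbfb does not. Csf2rb, Csf2rb2 and Gata2, which passed the filter outside the Cbfb+/MYH11 arrays too, rose in arrays 1 and 2 (3.88, 5.63 and 3.25) and in arrays 3 and 4 (4.26, 5.54 and 3.78). An origin in adult blood was argued against by the lack of a rise in granulocyte and lymphoid genes (bound of -0.231), most of which stayed dim. The mast cell list as a whole did not rise without the filter (median -0.03). Bulk arrays cannot tell more such cells from more transcript per cell. Sorting Csf2rb-positive cells from single embryos and counting Ms4a2 and Gata2 transcripts per cell would separate these.

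Most platelet and macrophage genes fell in both mutants, which may reflect a shared need for core binding factor activity in these lines, an absence of their cells or differences between pools. Without the filter the platelet median was 7.27 and 7.54 on WT arrays 1 and 2 but 5.65 and 5.76 on WT arrays 3 and 4, against at most 5.43 in Cbfb-/- and at least 7.02 in its littermates. The macrophage median likewise was 6.47 and 6.38 against 5.42 and 5.26 in WT, and 4.66 to 4.91 in Cbfb-/-. The medians of the platelet list were -1.82 and -1.83 with quantile normalization, and those of the macrophage list -1.81 and -2.23. Tubb1 and Itga2b fell in Cbfb-/- and not in Cbfb+/MYH11 and differed between the effects, so the fusion might leave part of the platelet programme in place. Of the 15 platelet genes 4 had a more positive effect in Cbfb+/MYH11, while Pf4 differed the other way (-1.99). The platelet list as a whole did not differ (camera adjusted p = 0.656). Counting CD41-positive cells in the blood of both mutants would test this.

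Chance splits of the arrays were compared with the real ones. For Cbfb+/MYH11, 1 of 35 splits, the real one, called 2671 genes. The highest other called 552 and followed the array pairs, which points to structure in the cross. Only 3 splits keep arrays 1 and 2, and 3 and 4, of a genotype together, too few for a share under 0.05. These were the real one, the one that follows the array pairs and a crossed one that called 4. For Cbfb-/- the 10 splits are too few for a share under 0.05, with 1935 for the real and 0 for the highest other. For the wild types 1 of 35 reached 831, the highest other being 647, which is the real split with WT array 1 moved to the Cbfb+/+ side. No other of these splits keeps WT arrays 1 and 2, WT arrays 3 and 4 and the Cbfb+/+ arrays together. The 1 of 35 is therefore no measure of chance. In 100 drawings 1, the real one, reached the 914 shared genes (highest other 3), 4 reached the 1548 genes of the difference (highest other 3346), 2 the 713 of Cbfb+/MYH11 only (1712), 6 the 394 of Cbfb-/- only (1245) and 2 the 95 opposite genes (385). For Cbfb-/- only the share is not under 0.05. The drawings exchanged single arrays and mostly broke the array pairs, so the lower shares of the other classes decide nothing either. The large drawings kept the real grouping of a cross whole. In the 83 that mixed both crosses the highest counts were 1 in the difference, 1 in Cbfb+/MYH11 only and 0 in the others. Mixing the arrays of a group puts real differences into the spread between arrays. These low counts thus followed largely from the construction and do not measure chance.

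Differences between pools could account for a part of the counts that arrays alone cannot bound. Averaged to putative pools, 18 genes remained in Cbfb+/MYH11, Csf2rb, Csf2rb2, Gata2 and Ms4a2 among them, and 0 elsewhere. Arrays from at least 3 separately collected pools per genotype would show which of the 1935 changes of Cbfb-/- recur.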
